A study of Homo sapiens with 4 samples.

How the data were processed

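Total RNA from HK2 cells was labelled with a fluorescent dye and hybridised to a 1-colour Agilent expression array, with 1 array for each of control, NaCl, urea and mannitol after 24 h. Groups were taken from the sample titles. Per the file headers and the submitters' processing notes, the authors scanned the arrays and extracted spot intensities with Agilent Feature Extraction 10.7.3.1. Per the file headers, the deposited intensity of each spot was background-subtracted with a spatial detrending model and multiplicatively detrended within its array, with surrogate values for spots not above their error, and it was not scaled between arrays. The 4 arrays lay on 1 slide and shared 1 scan day, scanner and protocol, so no batch split was possible, and the position on the slide and the group cannot be told apart. Each array held 174979 spots, of which 170635 measured 34127 probes in 5 spots each and 4295 were negative controls. Between 1.46% and 1.91% of the spots were marked as outliers. The number of arrays limits the precision: with 1 per group no variation between cultures can be estimated, no paired analysis was possible, and no test or p-value is given.

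Outlier spots were left out, and the median log2 intensity of a probe's remaining spots was taken. Each array was scaled by subtracting the 75th percentile of its log2 intensities. The median spread between spots of a probe was 0.0676 to 0.0717 (SD, log2) for detected genes, and the printed standard errors come from this spread. Gene names were updated through RefSeq accessions for 26373 probes, through symbols for 2226 and through synonyms for 343, and 5185 probes kept the name in the files. This gave 25965 genes or unnamed targets, both counted as genes here, of which 19953 had a symbol the naming rule accepts. For the 6336 genes with more than 1 probe, the probe with the highest mean log2 intensity stood for the gene. Of 79 named ratios with more than 1 detected probe, 18 had probes more than 1 apart on the log2 scale and 10 had probes on both sides of 0.

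A gene was measured in a comparison where most of its spots were well above background on at least 1 of the 2 arrays. Where it was not on the other array, the dimmer value was replaced by the higher of its own signal and the lowest signal among probes well above background there, and the ratio is given as a lower bound ("at least"). Genes were called by size alone, at a ratio of 2-fold. Of the called genes, 99.3% to 99.9% had spots that did not overlap between the 2 arrays, by comparison. Given the small spread between spots, the 2-fold rule all but fixes this share, so it is no check on the calls. All 6 pairs of arrays were compared. Correlations across genes used the 18601 detected on all 4 arrays. Since ratios to control share an array, overlaps and correlations were also computed after shuffling the 4 values within each gene 100 times, with other arrays as the reference and for ratios that share no array.

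The 27 gene lists covered osmoprotective genes, heat shock proteins, the unfolded protein and integrated stress response, NRF2 and oxidative stress, metallothioneins, p53 targets, cell cycle, cytokines and chemokines, interferon response, antigen presentation, matrix and fibrosis, epithelial junctions, mesenchymal genes, tubule injury, proximal tubule function, ion transport, aquaporins and urea transport, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, immediate early genes, EGF family and MAPK feedback, apoptosis, autophagy and lysosome, ribosomal proteins, the respiratory chain and markers of other cell types. Some genes are in more than 1 list. The median ratio of a list, with bounds at their bound, was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The random range spans the 2.5 to 97.5 percentiles and describes these arrays, and it is not a test. The lists, the groups, the rule for called genes, the naming rule and all 10 alternatives were fixed before the data were examined.

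The naming rule took, for each osmolyte against control, the 10 called genes with the largest ratio in each direction that had a symbol and whose brighter array lay at or above the median of detected genes. It also took up to 4 called members of each list, 5 genes in each direction for each other comparison, and the 5 in each direction with the largest smallest ratio over the 3 osmolytes. Named whatever their value were AKR1B1, SLC5A3, SLC6A6, SLC6A12, HSPA4L, NFAT5, HSPA1B, SGK1, GAPDH, ACTB and HPRT1. Positions are those of the probes in the array design (hg19).

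The alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the median of detected probes, the authors' value table, no filter on dim probes, only genes detected on all 4 arrays, the mean of all probes of a gene, the mean of spots, and thresholds of 1.5-fold and 3-fold. The authors' deposited value table holds 1 intensity per probe. Set against the scanner files (r = 0.995 to 0.996 on the log2 scale), its values were whole numbers scaled to a 75th percentile of 1500 with a minimum of 5, not centred by gene. Its column medians were 150 for control, 153 for NaCl, 140 for urea and 152 for mannitol. How the authors combined spots is not given in the sources used here. The procedure was tested on simulated data with every array at the control array's level, apart from the simulated changes. Noise came from the spread between spots alone. In these data 50 of 50 genes were recovered at each of 4 simulated sizes, all past 2-fold. Of 19048 unchanged genes 5 were called, and 94 of 100 lists of random unchanged genes stayed inside their range. No variation between cultures was simulated, so these counts do not show how often genes are called between single cultures without a treatment effect. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.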

Results

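HK2 cells, an established line of human kidney proximal tubule cells, were cultured for 24 h in medium of 328 mOsm/L alone or with added NaCl, urea or mannitol. The submitters describe the 3 additions as isoosmolar, and the labels give no concentrations. RNA from each condition was measured on a 1-colour Agilent array that carried 34127 probes in 5 spots each. There was 1 array per group and 4 arrays in all, so no difference below has a replicate check, and no test across samples was possible. The error after each log2 ratio is the standard error over the probe's spots on the 2 arrays compared, up to 5 per array without outliers. It is that of a difference of means, while the ratio is a difference of medians, whose own error was not computed. The printed error covers spot noise and leaves out variation between cultures. Ratios are on the log2 scale unless a fold is given. A gene is called higher or lower where its ratio was at least 2-fold. Orders of size are among called genes with a symbol whose brighter array lay at or above the median of detected genes. Ratios of genes that were dim on 1 array depend on the background step, and where normexp background correction moved a named ratio by 2-fold or more its value is given beside it. The share of spots well above background was 73.9% for control, 74.8% for NaCl, 74.0% for urea and 76.3% for mannitol, and no spot was saturated.

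The NaCl and mannitol arrays resembled each other more than either resembled the rest. Across the 18601 genes and unnamed targets detected on all 4 arrays, their log2 signals had a Pearson correlation of 0.995. The other pairs lay between 0.969 for mannitol with control or urea and 0.983 for urea with control. These correlations are across genes, which are not independent replicates.

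The NaCl comparison asks which genes differed after 24 h of added salt. Several genes that bring in or make organic osmolytes were higher with NaCl than in control. SLC6A12, the betaine transporter, was 138-fold higher (7.11 ± 0.04), and SLC5A3, the myo-inositol transporter, was 17.5-fold higher (4.13 ± 0.06). AKR1B1, the aldose reductase that makes sorbitol, was 2.54-fold higher (1.35 ± 0.03), and NFAT5, the transcription factor of the tonicity response, was 2.26-fold higher (1.18 ± 0.04). Of the 22 measured osmoprotective genes, 12 were higher and 0 lower, with a median of 1.11 against a random range of −0.25 to 0.20. Others among them were S100A4 (3.13 ± 0.03), also in the mesenchymal list, and the amino acid transporter SLC38A2 (2.19 ± 0.04). The brighter SLC6A6 probe, for the taurine transporter, gave 0.59 ± 0.05 and its other probe 2.58. HSPA4L gave 0.08 ± 0.04 and SGK1 −0.22 ± 0.04. The probe of SLC6A12 lies on chromosome 12 at 299740 to 299799, that of SLC5A3 on chromosome 21 at 35478440 to 35478499, and that of NFAT5 on chromosome 16 at 69738311 to 69738370, in hg19 coordinates of the array design.

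**Figure D1:**
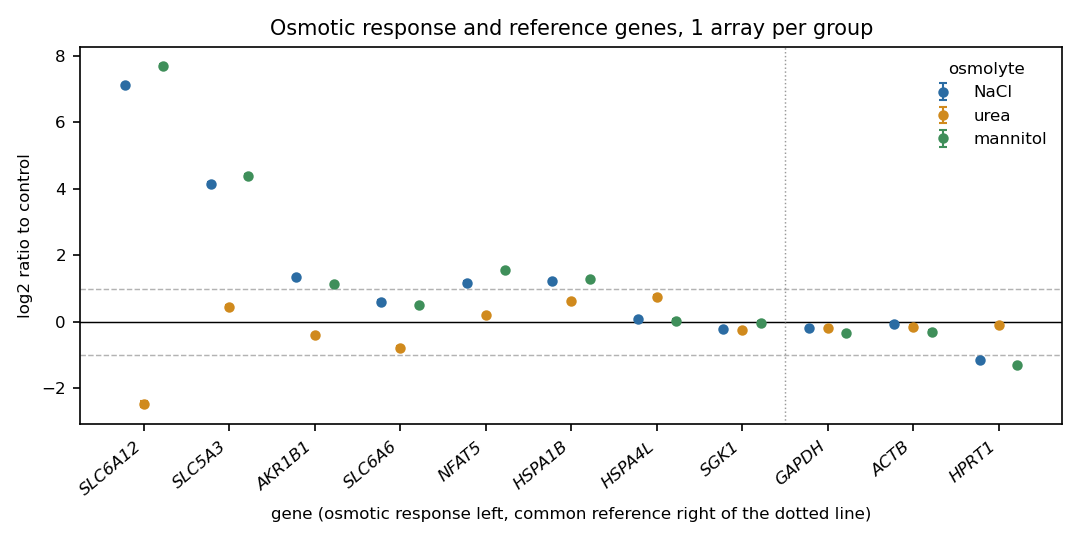
Log2 ratio to control (y axis) of the 8 osmotic response genes and 3 common reference genes (x axis), by osmolyte. Bars are standard errors over up to 5 spots per array, mostly smaller than the points, and dashed lines mark 2-fold. SLC6A12 was at 7.11 with NaCl and 7.70 with mannitol and at −2.48 with urea.

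In all, 1131 genes were higher and 1131 lower with NaCl among 19758 measured. The protease-like gene PRSS35 had the largest ratio (9.26 ± 0.09, and 8.16 with normexp background correction). It was followed by SLC6A12 and by the microRNA host transcript MIR100HG, which was not well above background in control and was at least 80.2-fold higher (log2 of 6.32, and 4.21 with normexp background correction). Others among the 10 highest were AKR1C1, an aldo-keto reductase (6.13 ± 0.05), PAQR5, a membrane progestin receptor (5.09 ± 0.06), WFDC21P (4.77 ± 0.07) and FGFBP1, an FGF-binding protein (4.73 ± 0.03). KLRC4 (4.03 ± 0.05) and KLRC1 (4.02 ± 0.08) encode closely related lectin-like receptors, and AKR1C1 has close paralogs as well, so probes of these genes can also bind each other's transcripts. The lowest genes included SCEL (−4.54 ± 0.03), TXNIP, an inhibitor of thioredoxin (−3.44 ± 0.02), the transporter SLC16A9 (−3.33 ± 0.04), CLDN2, a pore-forming claudin of the proximal tubule (−2.91 ± 0.01) and SMC1B (−2.86 ± 0.04). TTC12 (−2.74 ± 0.07), SDSL (−2.72 ± 0.06), ITGB4 (−2.67 ± 0.05) and FLRT3 (−2.61 ± 0.05) were also among the 10 lowest.

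Heat shock proteins, NRF2 genes and cytokines lay above their random ranges with NaCl, while the unfolded protein and integrated stress response lay inside its range (median −0.09; 2 of 24 higher, 3 lower). Of 18 heat shock proteins, 5 were higher and 0 lower (median 0.56, random range −0.26 to 0.15), among them CRYAB (2.67 ± 0.04), HSPH1 (2.10 ± 0.02) and HSPA1B (1.23 ± 0.02), a near copy of HSPA1A. Of 25 NRF2 and oxidative stress genes, 7 were higher and 0 lower (median 0.36, random range −0.22 to 0.18), among them the export pump ABCC2 (3.42 ± 0.15, and 1.72 with normexp background correction) and AKR1B10 (3.15 ± 0.03). Of 26 cytokine and chemokine genes, 7 were higher and 2 lower (median 0.48, random range −0.23 to 0.24). CSF1 (2.43 ± 0.03, and up to 4.42 by its other probes), CCL2 (2.04 ± 0.07) and TNF (1.59 ± 0.03) were higher, and so was IL1A (2.83-fold), which was under 2-fold with normexp background correction (0.52).

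A total of 6 fixed groups lay below their random ranges with NaCl. Of 27 interferon response genes, 8 were lower and 1 higher (median −0.43, random range −0.24 to 0.22): IFI44L (−2.23 ± 0.05) and IFI44 (−2.12 ± 0.03) were lower, and IFI27 was higher (1.79 ± 0.09). Of 10 metallothioneins, 4 were lower and 0 higher (median −0.46, random range −0.31 to 0.19), with MT1M at −1.61 ± 0.03. Of 29 genes of glycolysis and the hypoxia response, 6 were lower and 1 higher (median −0.42, random range −0.22 to 0.13). PDK1 (−2.38 ± 0.04), NDRG1 (−2.04 ± 0.02) and the hexokinase gene that shares the name HK2 (−1.71 ± 0.04) were lower, and VEGFA was higher (1.84 ± 0.06). Of 25 respiratory chain genes, 3 were lower and 0 higher (median −0.41, random range −0.23 to 0.14), with NDUFV1 at −1.15 ± 0.02. Of 32 matrix genes, 5 were lower and 3 higher (median −0.27, random range −0.21 to 0.14); with no filter on dim probes the median was −0.11, inside its range. Of 26 proximal tubule genes, 3 were lower and 0 higher (median −0.21, random range −0.20 to 0.26), with the bicarbonate cotransporter SLC4A4 at −1.17 ± 0.01. COL5A1 was lower (−1.95 ± 0.02), but its 3 probes ranged from −2.07 to 0.01.

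Single members of other lists differed with NaCl while the list median stayed inside its range. AQP3, a water and glycerol channel, was higher (4.61 ± 0.06, and 3.34 with normexp background correction), and ARG2, the mitochondrial arginase, was higher (2.41 ± 0.03), while CPS1 was lower (−1.43 ± 0.04). STK39, a kinase that acts on cation-chloride cotransporters (2.67 ± 0.05), ATP1B1, a subunit of the sodium pump (1.85 ± 0.10), and the potassium channel KCNK5 (1.80 ± 0.03) were higher. ATP1B1 and KCNK5 are also in the osmoprotective list, which lay above its range. EGR1 was lower (−2.50 ± 0.03), and KLF4 (1.52 ± 0.04) and FOSB (1.49 ± 0.04) were higher. CLDN1 (1.68 ± 0.03) and CDH16 (1.62 ± 0.03) were higher, and CDH6 was lower (−1.73 ± 0.02). The lysosomal channel MCOLN1 was higher (1.65 ± 0.03), and BCL2 was lower (−1.63 ± 0.03) by its brighter probe, with −0.39 by the other. ACTA2 was lower (−1.85 ± 0.10), though under 2-fold with normexp background correction (−0.90). Of the common reference genes, HPRT1 was 2.20-fold lower (−1.14 ± 0.02), GAPDH gave −0.18 ± 0.02 and ACTB −0.05 ± 0.05, whose sign turned with normexp background correction (0.04) and in the authors' value table (0.01).

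The mannitol comparison asks what a sugar alcohol that adds no salt did at the same added osmolality. The same osmolyte genes were higher with mannitol as with NaCl. SLC6A12 was 208-fold higher (7.70 ± 0.04), SLC5A3 20.8-fold (4.38 ± 0.05), NFAT5 2.93-fold (1.55 ± 0.03) and AKR1B1 2.18-fold (1.12 ± 0.04). Of the 23 measured osmoprotective genes, 11 were higher and 1 lower (median 0.86, random range −0.33 to 0.24), among them S100A4 (3.03 ± 0.03) and KCNK5 (2.83 ± 0.03). The brighter SLC6A6 probe gave 0.50 ± 0.05 and its other probe 2.25. HSPA4L gave 0.03 ± 0.04 and SGK1 −0.03 ± 0.04.

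With mannitol, 1712 genes were higher and 1572 lower among 20056 measured, a share of 47.9% lower. This split depends on the scaling: centring on the median of detected probes moved the median of all genes by 0.18 and gave 2403 higher and 1055 lower, or 30.5% lower. PRSS35 had the largest ratio (9.05 ± 0.10, and 7.90 with normexp background correction). CALB1, the calcium-binding protein calbindin and a marker of the distal nephron, was not well above background in control and was at least 218-fold higher (log2 of 7.77), and with NaCl at least 76.4-fold (6.26). With normexp background correction these 2 ratios were 5.61 and 4.13. MIR100HG was at least 148-fold higher (7.21, and 5.10 with that correction). AKR1C1 (6.15 ± 0.05), WFDC21P (5.37 ± 0.06), PAQR5 (5.02 ± 0.06), DIRC3 (4.96 ± 0.14, and 3.58 with it), the transcription factor CREB3L3 (4.79 ± 0.04) and the guanylate cyclase subunit GUCY1A2 (4.56 ± 0.14) were also among the 10 highest. The lowest included TXNIP (−4.25 ± 0.02), SCEL (−4.09 ± 0.05), FLRT3 (−3.87 ± 0.06), CLDN2 (−3.45 ± 0.01), TTC12 (−3.17 ± 0.05), SDSL (−3.15 ± 0.06), SMC1B (−3.14 ± 0.05), IFI44 (−3.08 ± 0.04) and IFI44L (−3.07 ± 0.06). The CALB1 probe lies on chromosome 8 at 91071700 to 91071759, that of PRSS35 on chromosome 6 at 84234849 to 84234908 and that of TXNIP on chromosome 1 at 145442447 to 145442506 (hg19).

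Of 18 heat shock proteins, 6 were higher and 0 lower with mannitol (median 0.55, random range −0.36 to 0.11), among them HSPH1 (2.47 ± 0.04) and HSPB8 (1.79 ± 0.02); HSPA1B gave 1.30 ± 0.03. Of 25 NRF2 genes, 7 were higher and 1 lower (median 0.35, random range −0.32 to 0.17), among them AKR1B10 (3.67 ± 0.04) and SOD2, the mitochondrial superoxide dismutase (2.86 ± 0.05). Of 27 cytokine and chemokine genes, 9 were higher and 3 lower (median 0.41, random range −0.29 to 0.30), with CCL2 at 2.68 ± 0.06 and VCAM1 at −2.32 ± 0.04. Of 28 ion transport genes, 6 were higher and 1 lower (median 0.40, random range −0.31 to 0.22), among them STK39 (2.77 ± 0.05), the scaffold NHERF1 (1.95 ± 0.01) and ATP1B1 (1.91 ± 0.10). Of 18 EGF family and MAPK feedback genes, 4 were higher and 2 lower (median 0.43, random range −0.38 to 0.33), with DUSP6 at 1.43 ± 0.03 and SPRY1 at −2.10 ± 0.03. AQP3 was higher (4.82 ± 0.07, and 3.5 with normexp background correction), and KLF4 was 6.58-fold higher (2.72 ± 0.03).

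Below their random ranges with mannitol were the metallothioneins (median −0.66 against −0.40 to 0.18; 4 of 10 lower), the respiratory chain (median −0.46 against −0.32 to 0.11; 4 of 25 lower) and the matrix genes (median −0.44 against −0.29 to 0.12; 8 of 32 lower, 2 higher). MT1M was at −1.71 ± 0.04, NDUFB5 at −1.29 ± 0.02 and COL1A1 at −2.23 ± 0.06. With no filter on dim probes the matrix median was −0.15, inside its range. The mesenchymal list (median −0.40 against −0.37 to 0.24; 5 of 18 lower, 1 higher) and the tubule injury list (median −0.36 against −0.35 to 0.18; 4 of 19 lower, 3 higher) were just outside. Under quantile normalization their medians were −0.24 and −0.21, inside their ranges. Both were also inside with normexp background correction, the first also with the mean of all probes, and the second also in the value table and with no filter on dim probes. The interferon list was inside its range with mannitol (median −0.18; 8 of 27 lower, 3 higher). HPRT1 was 2.45-fold lower (−1.29 ± 0.02), and GAPDH and ACTB gave −0.33 ± 0.03 and −0.31 ± 0.06. RRM2 was lower by its brighter probe (−1.13 ± 0.05), while its other probe gave 1.61.

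**Figure D2:**
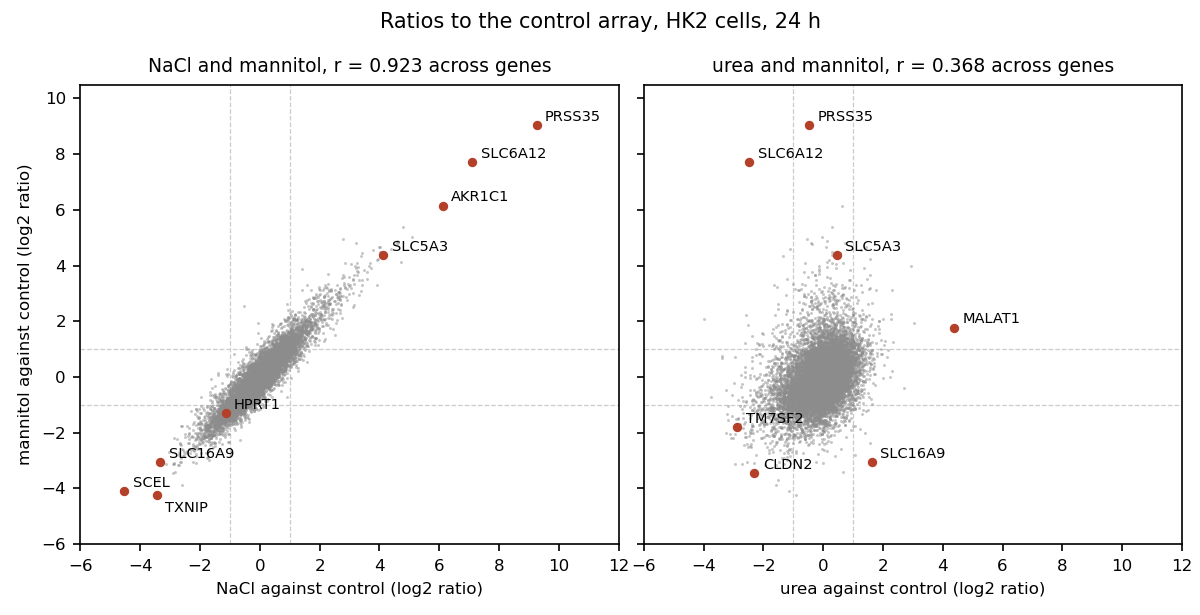
Log2 ratio to control of each gene or unnamed target detected on all 4 arrays, with mannitol on the y axis and NaCl (left) or urea (right) on the x axis; red points are named genes and dashed lines mark 2-fold. The NaCl and mannitol ratios lay along the diagonal (r = 0.923), the urea and mannitol ratios did not (r = 0.368).

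Set against each other, NaCl and mannitol differed in few genes. Only 48 genes were higher with NaCl and 236 higher with mannitol among 19859 measured. These counts depend on the processing: they were 18 and 59 with normexp background correction, 16 and 370 with median centring, and 178 and 549 with no filter on dim probes. The genes higher with NaCl included the cytokine IL11 (1.63 ± 0.04), AKAP12 (1.29 ± 0.02), VCAM1 (1.29 ± 0.05), the EGF receptor ligand AREG (1.22 ± 0.03) and CDH6 (1.13 ± 0.02, and 0.99 with median centring). Those lower with NaCl included DIRC3 (−2.17 ± 0.02), CREB3L3 (−1.58 ± 0.03), NEFM, a neurofilament subunit (−1.52 ± 0.06), CALB1 (−1.51 ± 0.04) and the bile acid receptor NR1H4 (−1.40 ± 0.02). SLC6A12 gave −0.60 ± 0.03, SLC5A3 −0.25 ± 0.04 and NFAT5 −0.37 ± 0.04, all under 2-fold. Cholesterol synthesis genes had a median of 0.30, above the random range of −0.08 to 0.15, with 0 of 24 at least 2-fold apart, and the matrix genes had a median of 0.19, above −0.03 to 0.14, with 0 of 32 apart. Fatty acid synthesis (0.22), metallothioneins (0.20) and mesenchymal genes (0.20) also lay above their ranges, and glycolysis and the hypoxia response (−0.15), ion transport (−0.13) and NRF2 genes (−0.05) below theirs, the last at its edge (percentile 2.49). At most 1 member of each of these lists was 2-fold apart. The NaCl to mannitol ratio had a Spearman correlation of 0.245 with probe GC content across genes. The random lists were not matched on GC content, and whether list shifts of this size follow that trend was not tested. Of the genes higher with NaCl than control, 990 or 87.6% were also higher with mannitol. Of the genes lower with NaCl, 972 or 85.9% were also lower with mannitol. No gene was higher with one of these osmolytes and lower with the other. Because both ratios use the control array, some overlap can arise from that array alone. Shuffling the 4 values within each gene gave 413 shared higher and 441 shared lower genes on average over 100 shuffles. The shuffle keeps each gene's differences between arrays and only reassigns them, so these counts do not measure the part due to the control array.

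The ratios to control of NaCl and mannitol had a Pearson correlation of 0.923 across genes, against 0.501 on average after shuffling. That 0.501 is close to what shuffled values with a shared reference give by construction, so it does not measure noise of the control array. The NaCl to control ratio and the mannitol to urea ratio, which share no array, had a correlation of 0.675. That of the mannitol to control and NaCl to urea ratios, which share none either, was 0.541.

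The urea comparison asks what an osmolyte that crosses cell membranes did. The osmolyte transporters were not higher with urea. SLC5A3 gave 0.45 ± 0.05, AKR1B1 −0.38 ± 0.01 and NFAT5 0.21 ± 0.03, and SLC6A12 was 5.57-fold lower (−2.48 ± 0.09). SLC6A12 was dim with urea, and its ratio was −0.87 with normexp background correction. Of 22 osmoprotective genes, 0 were higher and 1 lower (median −0.01, random range −0.26 to 0.18). SLC6A6 gave −0.78 ± 0.05 by its brighter probe and 0.25 by the other, HSPA4L 0.76 ± 0.04, HSPA1B 0.63 ± 0.03 and SGK1 −0.25 ± 0.03. HPRT1 (−0.08 ± 0.02), GAPDH (−0.19 ± 0.03) and ACTB (−0.14 ± 0.05) were all within 2-fold of control.

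With urea, 508 genes were higher and 1321 lower among 19598 measured, so 72.2% of the genes 2-fold apart were lower. The largest ratio was that of MALAT1, an abundant nuclear non-coding RNA, at 20.9-fold (4.38 ± 0.04); its probe lies on chromosome 11 at 65272873 to 65272932 (hg19). The next in size were RCBTB2 (2.29 ± 0.04), VAMP1 (2.28 ± 0.03), RSRP1 (2.14 ± 0.06), the ATP-gated channel P2RX5 (2.03 ± 0.04), TFRC, the transferrin receptor (2.02 ± 0.04), SNHG1, a host transcript of small nucleolar RNAs (1.93 ± 0.03), the phosphodiesterase PDE11A (1.74 ± 0.05) and WSB1 (1.72 ± 0.07). INF2 gave 1.87 ± 0.03 by its brightest probe, while its 3 probes ranged from −0.57 to 1.87. The lowest genes were PIGQ, of GPI anchor synthesis (−3.05 ± 0.05), TM7SF2, a sterol reductase (−2.88 ± 0.08), AMDHD2 (−2.86 ± 0.04), the sulfotransferase GAL3ST1 (−2.73 ± 0.04), the mitochondrial carrier UCP2 (−2.73 ± 0.05), MTURN (−2.72 ± 0.05), the choline kinase CHKB (−2.67 ± 0.08), HSD17B8 (−2.67 ± 0.06), the ribokinase RBKS (−2.66 ± 0.04) and CIMAP1B (−2.63 ± 0.04). The other MTURN probe gave −1.17.

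Genes of cholesterol synthesis were lower with urea as a group. Of 24 measured, 8 were lower and 0 higher (median −0.73, random range −0.24 to 0.20), among them LSS, which closes the sterol ring (−1.57 ± 0.05), PMVK (−1.34 ± 0.03) and MVD (−1.30 ± 0.02) of the mevalonate pathway. Of 28 epithelial junction genes, 8 were lower and 0 higher (median −0.62, random range −0.25 to 0.16), among them CLDN2 (−2.30 ± 0.02), the tight junction scaffold TJP3 (−2.23 ± 0.08) and MUC1 (−1.69 ± 0.05). Also below their random ranges were glycolysis and the hypoxia response (median −0.38 against −0.25 to 0.09; 3 of 29 lower), with PDK1 at −2.41 ± 0.04, the unfolded protein and integrated stress response (median −0.28 against −0.22 to 0.20; 0 of 24 lower, 1 higher) and the respiratory chain (median −0.28 against −0.24 to 0.12; 0 of 25 lower).

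Heat shock proteins lay above their range with urea, although 0 of 18 reached 2-fold (median 0.38, random range −0.27 to 0.11). Cell cycle genes lay above it too (median 0.26, random range −0.21 to 0.13; 1 of 33 higher), with CDC6 at 1.03 ± 0.03, and 0.92 with normexp background correction. Immediate early genes were just above it (median 0.24, random range −0.28 to 0.22; 2 of 21 higher, 1 lower), with JUN at 1.23 ± 0.03, but inside their range under 4 of the 8 alternatives: normexp background correction (median 0.21), genes detected on all 4 arrays (0.24), the mean of all probes (0.24) and the mean of spots (0.21). The NRF2 list was inside its range (median 0.04; 4 of 25 higher), with AKR1B10 at 1.57 ± 0.04, NQO1 at 1.29 ± 0.03 and TXNRD1 at 1.05 ± 0.03. Among single members of other lists, the matrix proteases MMP13 (−2.62 ± 0.06, and −1.5 with normexp background correction) and MMP1 (−1.70 ± 0.06), and the urea cycle enzymes ASL (−2.46 ± 0.03) and ASS1 (−1.16 ± 0.06) were lower. SLC16A9 (1.62 ± 0.04), ANGPTL4 (1.58 ± 0.04) and CPT1A, the entry enzyme of fatty acid oxidation (1.44 ± 0.03), were higher.

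**Figure D3:**
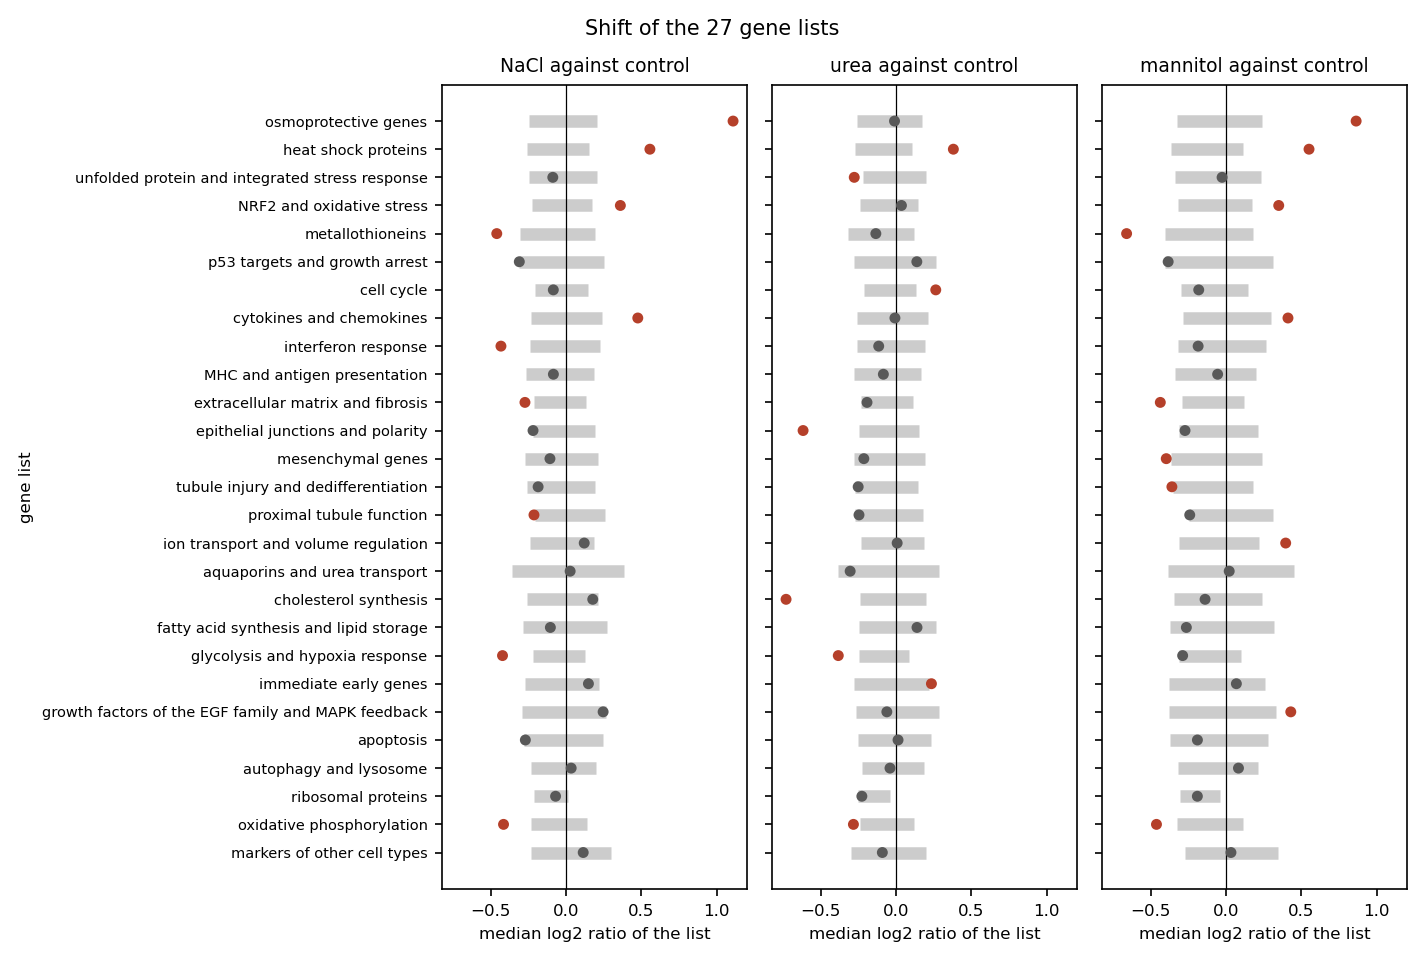
Median log2 ratio to control of the measured members of each of the 27 gene lists (points), by osmolyte; grey bars span the central 95% of 10000 random lists matched on expression, and red points lie outside them. The osmoprotective list was at 1.11 with NaCl, −0.01 with urea and 0.86 with mannitol.

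Of the 27 lists, 10 lay outside their random range with NaCl, 8 with urea and 11 with mannitol. For lists of unrelated genes 1.35 would be expected. These lists hold genes that can vary together and share some members, so 1.35 is not the number expected of them without a treatment effect. A total of 8 lists were inside their range with all 3 osmolytes. In the order NaCl, urea and mannitol, their medians were −0.31, 0.14 and −0.38 for p53 targets, −0.08, −0.08 and −0.06 for antigen presentation, and 0.03, −0.30 and 0.02 for aquaporins and urea transport. They were −0.10, 0.14 and −0.26 for fatty acid synthesis, −0.27, 0.01 and −0.19 for apoptosis, 0.03, −0.04 and 0.08 for autophagy and lysosome, and −0.07, −0.23 and −0.19 for ribosomal proteins. Markers of other cell types gave 0.11, −0.09 and 0.03. Ratios of single markers included CSF1R at −1.49 ± 0.02, −1.58 ± 0.03 and −1.48 ± 0.04, and CALB1 as given above.

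Urea differed from mannitol by 1224 higher and 1993 lower genes among 20053 measured. SLC6A12 (−10.18 ± 0.08), PRSS35 (−9.53 ± 0.05) and the potassium channel-interacting protein KCNIP1 (−6.05 ± 0.04) were far lower with urea than with mannitol. All 3 were dim with urea, so the size of these ratios depends on the background step: with normexp background correction they were −7.91, −8.04 and −4.66. CALB1 and MIR100HG were at least 222-fold and at least 150-fold lower (−7.79 and −7.23), and −5.42 and −4.90 with that correction. SLC5A3 was 15.2-fold lower (−3.93 ± 0.04) and AKR1B1 2.84-fold lower (−1.51 ± 0.04). The highest included SLC16A9 (4.67 ± 0.04), HGD, an enzyme of tyrosine breakdown (3.43 ± 0.04), TXNIP (3.35 ± 0.02) and IFI44 (3.08 ± 0.03). Of 23 osmoprotective genes, 11 were lower and 1 higher (median −0.91, random range −0.25 to 0.24). Cholesterol synthesis genes were lower too (median −0.50, random range −0.23 to 0.29; 6 of 24 lower, 0 higher). Metallothioneins (median 0.46; 3 of 10 higher) and cell cycle genes (median 0.34; 4 of 33 higher) lay above their ranges of −0.24 to 0.24 and −0.15 to 0.22, and cytokines and chemokines below theirs of −0.31 to 0.22 (median −0.40; 9 of 27 lower, 4 higher).

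NaCl differed from urea by 1713 higher and 1062 lower genes among 19718 measured. PRSS35 (9.73 ± 0.05, and 8.31 with normexp background correction) and SLC6A12 (9.58 ± 0.09, and 7.31) were higher, as were AKR1C1 at 45.4-fold (5.50 ± 0.04), PAQR5 at 35.5-fold (5.15 ± 0.06) and MIR100HG at least 81.5-fold (6.35, and 4.02 with that correction). SLC16A9 (−4.95 ± 0.04), EGR1 (−3.26 ± 0.02), TAMM41 (−2.88 ± 0.03) and WSB1 (−2.85 ± 0.07) were among the lowest. Cholesterol synthesis genes were higher with NaCl than with urea (median 0.76, random range −0.23 to 0.25; 8 of 24 higher, 0 lower), and cell cycle genes lay below their range (median −0.33, random range −0.16 to 0.19; 2 of 33 lower, 0 higher). Also above their ranges were the osmoprotective list (median 0.83; 10 of 22 higher, 0 lower), NRF2 genes (0.24; 8 of 25 higher, 1 lower) and cytokines and chemokines (0.30; 5 of 26 higher, 0 lower). Metallothioneins (−0.24; 2 of 10 lower, 0 higher) and matrix genes (−0.14; 3 of 32 lower, 4 higher) lay below theirs.

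With all 3 osmolytes, 114 genes were higher and 347 lower than in control. The counts were 36 and 210 with normexp background correction, and 202 and 394 with no filter on dim probes. PTX3, a secreted pattern recognition protein, was higher by 2.08 ± 0.02 with NaCl, 1.64 ± 0.03 with urea and 2.66 ± 0.02 with mannitol. In the same order, MALAT1 gave 1.98 ± 0.04, 4.38 ± 0.04 and 1.77 ± 0.04, CDC42EP3 2.41 ± 0.03, 1.20 ± 0.03 and 2.23 ± 0.03, and STXBP5 1.36 ± 0.03, 1.25 ± 0.04 and 1.96 ± 0.04. CLDN2 was the first of the lower genes, at −2.91 ± 0.01, −2.30 ± 0.02 and −3.45 ± 0.01. SMIM1 gave −2.53 ± 0.05, −2.24 ± 0.05 and −2.78 ± 0.05, and GSTZ1, an enzyme of tyrosine breakdown, −2.09 ± 0.03, −2.49 ± 0.03 and −2.11 ± 0.03. SPACA9 and ACAD11 were each lower by 4.48-fold or more with every osmolyte. INF2 also met the rule among the higher genes, but its probes had opposite signs with each osmolyte. All 3 ratios share the control array. Shuffling the values within genes, under the main processing only, gave 125 to 179 higher and 149 to 207 lower genes. The higher count of 114 lay below the range of the shuffles and the lower count of 347 above it. With urea taken as the reference instead, 454 genes were higher and 153 lower on the other 3 arrays. These counts were 8 and 6 with NaCl as the reference, and 20 and 176 with mannitol.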

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

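The tests of the shared control array and of a response to effective hypertonicity were chosen only after the result was seen.

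Some genes were at least 2-fold apart from control in opposite directions with different osmolytes. With 1 array per group the difference between osmolytes was not tested in any of these cases. A total of 67 genes were higher with NaCl and lower with urea, among them SLC6A12, LOXL4, APCDD1L and KCNAB2, although SLC6A12 was dim with urea and its ratio to control was −0.87 there with normexp background correction. Another 28 were lower with NaCl and higher with urea, among them SLC16A14, RNF125, PTPN22, SLC16A9 and LEF1. With mannitol, 83 genes were higher where urea was lower, among them SLC6A12, LOXL4 and KCNIP1, which was also dim with urea. Another 22 were lower with mannitol and higher with urea, among them SLC16A14, SLC16A9 and HGD. These examples, apart from SLC6A12, SLC16A9, KCNIP1 and HGD, were chosen after their values were seen. Shuffling the values within genes gave 43.1 opposite genes on average for NaCl and urea, where 95 were seen, and 43.9 for urea and mannitol, where 105 were seen. The shuffle spreads the likeness of NaCl and mannitol, which had 0 opposite genes, over all pairs. These averages are therefore not counts expected by chance. All counts of opposite genes were made under the main processing only.

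NaCl and mannitol moved many of the same genes in the same direction relative to control, and urea shared fewer of them. Urea shared 168 higher genes with mannitol (shuffle range 370 to 465) and 133 with NaCl (372 to 482). It shared 509 lower genes with mannitol (414 to 493) and 384 with NaCl (400 to 487), so only the 509 lay above its range. Each of these counts lay above that expected of independent calls, which was 38.4, 26.0, 106.7 and 77.0 in the same order. Independent calls ignore the shared control array, and the shuffle spreads the likeness of NaCl and mannitol over all pairs. Neither is therefore a count expected by chance. Noise of the shared control array does not account for the likeness of NaCl and mannitol: ratios that share no array kept correlations of 0.675 and 0.541. Likeness of control and urea would also raise these values. Without the control array, the log2 difference of NaCl and mannitol had an SD of 0.307 across genes. It was 0.738 for NaCl and urea and 0.789 for urea and mannitol. The correlation of the NaCl and mannitol ratios to control was 0.926 after the median of each probe GC bin was subtracted. Those ratios had Spearman correlations of only −0.044 and −0.139 with GC content. With trends this weak the subtraction could hardly lower the correlation, so its result was all but fixed. A response to effective hypertonicity stays open. The median of −0.91 of the osmoprotective list for urea against mannitol follows from that list's ratios to control, which had already been seen, and so decides nothing. The single culture behind each array and its place on the slide stay open as well.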

How the results depend on the processing

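The 3 correlations between osmolytes kept their sign and stayed within 0.1 of the main value under all 8 alternatives that apply to them. Of these, median centring and the limit to genes detected on all 4 arrays could not change the correlations. The share of lower genes with urea ranged from 66.6% to 75% under the same 8 alternatives. It was 58.2% at 1.5-fold and 86.1% at 3-fold. Counts of genes were within 1.5 times the main count in 96 cases and outside it in 44, of which 28 follow from the threshold itself. With median centring the share of lower genes with mannitol was 30.5%, against 47.9%, since its median ratio shifted by 0.18. Normexp background correction added an offset of 50 to every intensity, which pulls the ratios of dim genes towards 0 by construction. Every count that it moved was smaller than the main count, and how much of the fall is due to the offset was not measured. The cause of the other moved counts was not tested, except that the dim probe filters change which genes are counted.

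With normexp background correction the counts were 645 higher for NaCl against control, 261 higher and 784 lower for urea, 1040 higher for mannitol, 18 higher and 59 lower for NaCl against mannitol, 1174 lower for urea against mannitol, 1000 higher for NaCl against urea, and 36 higher and 210 lower for all 3 osmolytes. Median centring gave 16 higher and 370 lower for NaCl against mannitol, no filter on dim probes gave 178 and 549 there and 202 higher for all 3 osmolytes, and genes detected on all 4 arrays gave 117 lower for NaCl against mannitol.

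At 1.5-fold the higher and lower counts were 2870 and 2727 for NaCl, 2028 and 2827 for urea, 3714 and 3582 for mannitol, 495 and 964 for NaCl against mannitol, 3023 and 3869 for urea against mannitol, 3423 and 2714 for NaCl against urea, and 596 and 1009 for all 3 osmolytes. At 3-fold they were 425 and 314, 66 and 409, 708 and 455, 1 and 42, 319 and 888, 724 and 264, and 11 and 63, in the same order.

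Of the ratios of named genes, 2542 moved by less than the spread between spots and 477 by more. RRM2 with mannitol reversed to 0.24 with the mean of all probes, since its 2 probes disagree. Of 337 named ratios past 2-fold, 308 stayed past it with normexp, 332 with quantile normalization, 322 with median centring and 335 in the value table. Of 336, 318 stayed past it with the mean of all probes. Of the 29 list shifts outside their range against control, 26 stayed outside with normexp and with no filter, 27 with quantile normalization and with the mean of all probes, 28 in the value table, with the mean of spots and among genes detected on all arrays, and 29 with median centring. Median centring moves a list and its random range alike, so its result was all but fixed. Signal over background limits the dim genes: 223 of the genes called for NaCl, 127 for urea and 353 for mannitol have only a lower bound.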

Other observations

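A total of 13 gene families were chosen by symbol after the values were seen, and their random ranges are descriptions, not tests. The median ratio of histone genes lay above its random range with each osmolyte: it was 0.41 with NaCl (24 of 72 at least 2-fold higher, 0 lower), 0.31 with urea (2 of 70 higher, 0 lower) and 0.51 with mannitol (31 of 72 higher, 2 lower). With urea the shift is in the median and few of the genes reached 2-fold. That of genes of cilia and flagella lay below its range, at −0.25 with NaCl (18 of 91 lower, 3 higher), −0.27 with urea (29 of 90 lower, 1 higher) and −0.25 with mannitol (25 of 95 lower, 4 higher). Both medians kept their sign and their place outside the range under all 8 alternatives to scaling, filter, probes and spots, although the cilium median with mannitol was −0.08 with median centring.

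Aldo-keto reductases, which reduce aldehydes and sugars, had a median of 1.41 with NaCl (7 of 12 higher, 1 lower), 1.73 with mannitol (7 of 12 higher, 3 lower) and −0.28 with urea (2 higher, 1 lower), inside the range of −0.33 to 0.29. With no filter on dim probes the medians for NaCl and mannitol were 0.11 and −0.03, inside their ranges. Killer cell lectin-like receptors, 6 measured genes grouped by symbol, had medians of 2.58 with NaCl and 2.82 with mannitol and 0.14 with urea. With no filter these were 0.79, 0.95 and −0.01 over 10 genes, the first 2 still above their ranges. KLRC1 and KLRC4 among them are closely related, and the sequences of the family were not compared.

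Zinc finger genes lay above their range with each osmolyte, at 0.09 with NaCl, 0.29 with urea (17 of 514 higher, 15 lower) and 0.14 with mannitol. The median urea ratio of all genes ran from 0.12 in the lowest quintile of probe GC content to −0.20 in the highest. The random lists were not matched on GC content. Glutathione S-transferases had a median of −0.66 with urea (4 of 16 lower, 0 higher) and −0.28 with NaCl (3 of 16 lower, 0 higher), both below their ranges, and −0.18 with mannitol (4 of 17 lower, 0 higher), inside it. With NaCl that median was −0.14 with normexp background correction and −0.24 in the value table, inside its range. Small nucleolar RNA host genes had medians of 0.36 with NaCl, 0.10 with urea and 0.72 with mannitol, and only the urea median was inside its range. That placement depends on the setting: with urea the median was 0.30 with no filter, 0.30 among genes detected on all 4 arrays and 0.48 with the mean of all probes, above its range, and with NaCl it was 0.20 with normexp background correction, inside its range.

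Of the other 6 families, HOX genes, aminoacyl tRNA synthetases and proteasome subunits lay inside their ranges with each osmolyte. Solute carriers lay just above with NaCl (0.08) and just below with urea (−0.12), keratins below with urea (−0.26) and SR splicing factors above with NaCl (0.29), with 0 of 12 at 2-fold. The solute carrier and keratin medians were inside their ranges under some alternatives.

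More genes were lower than higher with urea. The urea ratio had a Spearman correlation of −0.224 with probe GC content and 0.141 with gene span across genes. The split remained under other scalings and after subtracting these trends. The share of lower genes among those 2-fold apart was at its lowest 66.6% under quantile normalization and median centring. It was 71.8% after subtracting the median of each GC bin. After subtracting that of each gene span bin it was 71.5%, against 76.0% before it among the called genes with a known span. At 1.5-fold, with no subtraction, the share was 58.2%. Quantile normalization and median centring moved the median urea ratio by only 0.055 and 0.017, so a larger scaling error stays open. Quintile medians ran from 0.12 to −0.20 for GC content and from −0.15 to 0.05 for gene span. Trends this small could change few calls at 2-fold, so these subtractions could hardly end the split. Urea was also the lower side of most differences from mannitol and from NaCl (1993 lower and 1224 higher than with mannitol). No biological explanation was tested, and a fall in total RNA per cell would be hidden by the scaling.

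MALAT1 was 4.38 above control with urea on the log2 scale, far more than with NaCl or mannitol, beside RSRP1 at 2.14, WSB1 at 1.72 and PRPF38B at 1.38, the last named after its value was seen. A larger share of nuclear non-coding RNA in the urea sample would raise such RNAs as a class, but the median of annotated lncRNA genes was lower than that of protein-coding genes by a difference of −0.0541 (log2). The trend with probe GC content was small beside the ratios of MALAT1 and RSRP1, and the lower of their GC-corrected ratios was 2.16. The median urea ratio ran only from 0.12 to −0.20 over quintiles of GC content. Subtracting it could therefore not bring these ratios under 2-fold, and this result was fixed in advance. Among lncRNA genes 4.26% were higher and 9.87% lower with urea, against 2.19% and 7.38% of protein-coding genes. The excess of higher lncRNA genes is not particular to urea, with 10.1% against 5.32% for NaCl and 14.5% against 8.23% for mannitol, and differences between osmolytes were not tested. Where these transcripts lie in the cell was not measured, RNAs retained in the nucleus were not tested as a class of their own, and no biological explanation was tested.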
